A study of Homo sapiens with 18 samples.

How the data were processed

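A549 cells, a human non-small cell lung cancer line, were profiled on 18 Affymetrix whole-transcript arrays. Per the labels, cells transfected with a control siRNA or with siRNA against PKCiota and PKCzeta were grown in 10% serum and serum starved, exposed to 250 pM TGFβ for 1 h, washed, and kept for a further 7 h or 23 h in 0.2% serum, with 200 ng of RNA labelled per array. The 6 groups, each of 3 biological replicates, were the 2 siRNA arms without ligand, at 8 h and at 24 h; the untreated arrays carried no time in their labels. Per the submitters' processing notes the authors used RMA and Partek; the versions were not given in the sources used here.

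The deposited values were RMA intensity on a linear scale as the authors made it, from 21.2 to 51230, with column medians between 156.1 and 160.7. The plan of the analysis had assumed log2 values; since the values were linear, log2 was taken once before every test, and no other normalization was applied. The groups, comparisons, tests, gene lists and alternatives were fixed before the data were examined, except those that the text says were chosen afterwards. Of 28869 probe sets, 19310 carried 1 gene symbol, 1752 carried several and 7807 had none listed in the gene table used here. Only those with 1 symbol were tested, and where a gene had more than 1 the brightest stood for it, which left out 933 probe sets and gave 18377 genes. Of 8 marker genes fixed beforehand 7 were measured, and the other was not analysed here. No array was left out.

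Each gene was fitted with limma 3.58.1 in R 4.3.3, with 6 group means over all 18 arrays and empirical Bayes moderation with trend and robust off (12 residual and 18.1 total degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The 11 comparisons were TGFβ at 8 h and at 24 h against untreated in each arm, 24 h against 8 h in siControl, siPKCiz against siControl in each condition and as the mean of the 3 conditions, and the interaction of siRNA and TGFβ at each time. Every ± on a log2 change is the standard error from this fit unless SD is given. Array data have no read depth; the number of arrays, 3 per group, limits the precision, and the median standard error of a change against untreated was 0.10 log2 units.

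The genes named were chosen by a rule that always took PRKCI, PRKCZ and the marker genes. It then took the 10 highest and the 10 lowest called genes of the main comparisons (5 and 5 elsewhere). Where single groups were compared, only genes whose groups of arrays did not overlap were taken. In the mean of the conditions the arms could overlap. ODAPH, for instance, differed in the same direction in only 6 of 9 pairs of arrays. Last came up to 4 called members of each gene list with the largest change. For genes outside this rule the text says where they were chosen otherwise. The 25 gene lists, with 504 of 550 members measured, covered the silenced isoforms, other PKC isoforms, their partners and polarity proteins, TGFβ receptors and SMADs, TGFβ early target genes, BMP target genes, transcription factors of the epithelial to mesenchymal transition, mesenchymal markers, epithelial markers, extracellular matrix, integrins and actin cytoskeleton, cell cycle, p53 target genes, the unfolded protein and integrated stress response, interferon response, NF-kB target genes, YAP and TEAD target genes, sterol biosynthesis, hypoxia and glycolysis, NRF2 target genes, alveolar type 2 markers, histones and ribosomal proteins, and markers of leukocytes, fibroblasts and endothelium. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with the correlation estimated and with fry.

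The size of the response was measured in arrays held out of the ranking. The 200 genes with the largest change in siControl were ranked in 2 replicate numbers, and their mean signed change was read in each arm of the third. The whole procedure was tested on simulated data with 18377 genes and 18 arrays: for a change of 1 log2 unit 95.5% of genes were recovered at 24 h and 82.1% in the interaction, and for a simulated ratio of 0.7 the held-out ratio was 0.703. The simulated noise was independent between arrays, with no replicate that differed from the others. Overlaps of comparisons that shared untreated arrays were set beside 100 simulations with no effect. Arrays were also regrouped in other ways, 10 ways for 3 against 3 arrays and 100 for the larger designs, and the calls counted again.

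The alternatives tried were the replicate number as an additive factor, a filter on dim probe sets, quantile normalization, median centring, trend and robust moderation, array weights, a fold change of at least 1.5, only the arrays of the groups compared, all probe sets with 1 symbol, leaving out each array and each replicate number, and for the held-out ratio 50 or 500 genes and genes ranked in siPKCiz.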

Results

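A549 cells, an established human lung adenocarcinoma line, were transfected with a control siRNA (siControl) or with siRNA against the 2 atypical protein kinase C isoforms, PKCiota and PKCzeta (siPKCiz). Cells of each arm were left without ligand or given 250 pM TGFβ for 1 h and collected 8 h or 24 h after the start of the exposure, and their RNA was hybridised to whole-transcript expression arrays. There were 6 groups of 3 biological replicates, 18 arrays in all, with 18377 genes tested. Median deposited intensity per array lay between 156.1 and 160.7, and the number of arrays, 3 per group, limits the precision of every comparison. The labels give no time for the untreated arrays. Correlations between replicates of a group, across genes, lay between 0.992 and 0.998, and replicates 2 and 3 were the closest pair in 6 of 6 groups.

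PRKCI, which encodes PKCiota, was lower in siPKCiz by 2.24 ± 0.052 log2 units (SE, mean of the 3 conditions; 4.73-fold lower; limma adjusted p = 1.98e-15). Its intensity was 2469, 2163 and 2095 in siControl untreated replicates 1 to 3, and 513, 504 and 479 in siPKCiz. At 8 h of TGFβ it was 2804, 2818 and 2545 in siControl and 583, 621 and 554 in siPKCiz. At 24 h it was 2632.7, 2571.3 and 2815.2 in siControl and 457, 571 and 558 in siPKCiz. PRKCI in siPKCiz thus lay between 17.4% and 23.3% of the siControl array of the same number. PRKCZ, which encodes PKCzeta, fell by 1.07 ± 0.14 log2 units (SE; 2.10-fold lower; adjusted p = 3.43e-05), and its replicates differed. In untreated siControl its intensity was 265, 398 and 490 in replicates 1 to 3, and in untreated siPKCiz 242, 142 and 162. At 8 h the values were 309, 410 and 410 in siControl and 254, 153 and 153 in siPKCiz. At 24 h they were 302, 472 and 409 in siControl and 206, 189 and 152 in siPKCiz. PRKCZ in siPKCiz was 91.4%, 82.3% and 68.2% of siControl in replicate 1 and between 33.1% and 40.04% in replicates 2 and 3. Its intensity in the latter, 142 to 189, lay near the median of all probe sets on an array, 156.1 to 160.7. Background signal may limit these percentages, so they are not directly comparable with those of PRKCI. Of the 11 other PKC isoforms and related kinases measured, 3 rose and 2 fell over the 3 conditions, and 5 passed when adjusted over the list alone. PRKCQ, a T cell PKC isoform, rose by 0.59 ± 0.059 log2 units, and PRKCA fell by 0.20 ± 0.045 (SE; camera adjusted p for the list = 0.565). The list of the 2 silenced isoforms was lower with 2 of 2 fallen, 2 adjusted over the list alone (camera adjusted p = 7.08e-06; adjusted p = 0.00841 with an estimated correlation).

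**Figure D1:**
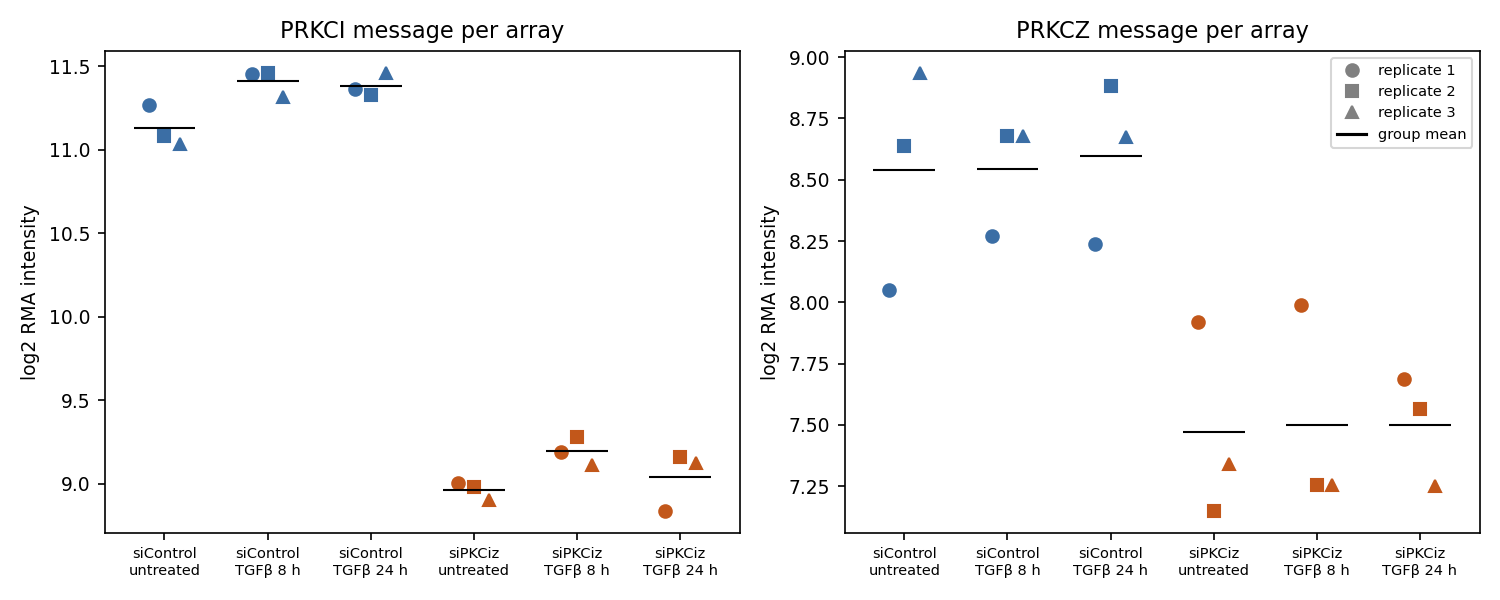
Log2 intensity of PRKCI and PRKCZ on each of the 18 arrays (vertical axis), by siRNA arm and condition, with replicate numbers marked. PRKCI was at 17.4% to 23.3% of control in each replicate, whereas PRKCZ in replicate 1 was at 68.2% to 91.4%.

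The first comparison asked which genes responded to TGFβ in control cells after 8 h. TNFAIP6, a secreted hyaluronan-binding protein, rose by 3.56 ± 0.45 log2 units (SE, n = 3 per group; 11.8-fold; adjusted p = 4.21e-05), SEMA7A, a membrane-anchored semaphorin, by 3.24 ± 0.27 (9.45-fold; adjusted p = 1.52e-06) and ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 3.02 ± 0.37 (8.11-fold). PDK4, a kinase that inhibits pyruvate dehydrogenase, fell by 2.69 ± 0.32 log2 units (6.46-fold lower; adjusted p = 2.83e-05), and the stem cell transcription factor SOX2 fell by 2.12 ± 0.39. The other genes with the highest rises were LCE3D, a cornified envelope protein (2.77), ODAPH (2.69), the Ras exchange factors RASGRP1 (2.55) and RASGRP3 (2.53), the xylosyltransferase GXYLT2 (2.50), TMEM88 (2.28) and R3HDML (2.24). The other genes with the deepest falls were TM4SF20 (-1.93), the nuclear receptor NR4A2 (-1.90), GPCPD1 (-1.87), the p38 kinase kinase MAP2K6 (-1.79), the fibrinogen chain FGA (-1.77), the bile acid conjugating enzyme BAAT (-1.71), the co-receptor TGFBR3 (-1.70) and the peptide hormone SPX (-1.63). By the rule for naming them, the 2 groups of 3 arrays did not overlap for these 20 genes, which chance gives in 10% of genes. PRKCI (0.28 ± 0.091) and PRKCZ (0.00 ± 0.24) were not called.

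Known TGFβ early target genes rose together at 8 h: of 33 measured, 27 rose, 0 fell and 6 were not called, and 29 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.8e-25; adjusted p = 0.0833 with an estimated correlation). ANGPTL4, PDGFB (1.99), SPHK1 (1.69) and CCN1 (1.45) had the largest rises in the list. Mesenchymal markers rose in 10 of 18 with 8 not called, 12 adjusted over the list alone (camera adjusted p = 7.24e-09; adjusted p = 0.0833 with an estimated correlation). They included the gelatinase MMP2 (1.86), the smooth muscle protein TAGLN (1.70), ITGA5 (0.98) and CALD1 (0.95). In the extracellular matrix list 14 of 39 rose and 0 fell, 16 adjusted over the list alone, with TIMP3 (1.94), COL4A1 (1.54), MMP10 (1.17) and COL1A1 (1.17) leading (camera adjusted p = 9.92e-08; adjusted p = 0.0959 with an estimated correlation). Among integrins and actin cytoskeleton genes 13 of 33 rose and 3 fell, 15 and 4 adjusted over the list alone (camera adjusted p = 1.33e-05; adjusted p = 0.147 with an estimated correlation). TNS1 (1.69), ITGB6 (1.33, and 0.86 without replicate 1), CNN1 (1.17) and ITGB3 (1.05) rose. Of 14 transcription factors of the epithelial to mesenchymal transition 5 rose and 2 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0343; adjusted p = 0.0959 with an estimated correlation). SNAI2 rose by 1.98 ± 0.18 and SNAI1 by 1.96 ± 0.18, TCF4 rose by 0.58 and SOX9 fell by 0.47. YAP and TEAD target genes had 6 risen and 3 fallen of 25, 7 and 4 adjusted over the list alone, with CCN2 at 1.25 and F3 at 0.77 (camera adjusted p = 0.0346; adjusted p = 0.403 with an estimated correlation).

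Sterol biosynthesis genes fell in 9 of 17 with 8 not called at 8 h, 11 adjusted over the list alone (camera adjusted p = 9.92e-08; adjusted p = 0.0959 with an estimated correlation), among them MVK (-0.66), MVD (-0.53), ACAT2 (-0.49) and LSS (-0.44). Of 19 NRF2 target genes 6 fell and 1 rose, 8 and 1 adjusted over the list alone (camera adjusted p = 0.000111; adjusted p = 0.166 with an estimated correlation). The transporter ABCC2 (-0.88), the glutathione synthesis enzyme GCLC (-0.52) and AKR1C2 (-0.49) fell, whereas HMOX1, heme oxygenase, rose by 1.17. Of 33 epithelial markers 10 fell and 5 rose, 10 and 6 adjusted over the list alone (camera adjusted p = 0.0371; adjusted p = 0.203 with an estimated correlation). E-cadherin (CDH1) fell by 0.96 ± 0.17, FGA and FGB (-1.29) fell, and the claudin CLDN4 rose by 1.54. Partners of the atypical PKCs and polarity proteins had 6 fallen of 20 and 0 risen, 6 adjusted over the list alone, including PARD6A (-0.78), PARD6B (-0.61), ECT2 (-0.59) and WWC1 (-0.56) (camera adjusted p = 0.0346; adjusted p = 0.166 with an estimated correlation). Interferon response genes had 6 fallen and 2 risen of 31, 9 and 3 adjusted over the list alone, with RIGI at -0.97 and OAS1 at -0.65 (camera adjusted p = 0.0245; adjusted p = 0.272 with an estimated correlation). NF-kB target genes and cytokines had 6 fallen and 2 risen of 23, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0407; adjusted p = 0.562 with an estimated correlation). CXCL1 fell by 1.18 and TNFAIP2 by 0.95, while IL1A rose by 1.94. Of 35 cell cycle genes 0 were called by limma, and the list shifted lower with a median of -0.12 (camera adjusted p = 0.0407; adjusted p = 0.829 with an estimated correlation); CDC6 was at -0.37 ± 0.16.

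Over all genes 951 rose and 1136 fell at 8 h in siControl, of which 126 and 88 by at least 2-fold (limma on 18 arrays, adjusted p under 0.05). The total of 2087 genes was 681 without replicate 2 and 802 without replicate 3. The remaining lists were not called by camera at 8 h, and the BMP target list came nearest (adjusted p = 0.0836), with BMP4 fallen by 1.45 and NOG risen by 1.11.

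At 24 h of TGFβ in control cells LCE3D rose by 4.22 ± 0.27 log2 units (SE, n = 3 per group; 18.6-fold; adjusted p = 2.36e-08), TNFAIP6 by 4.19 ± 0.45 (18.2-fold) and SLN, sarcolipin, an inhibitor of the sarcoplasmic calcium pump, by 3.67 ± 0.27 (12.7-fold; adjusted p = 1.49e-07). AGR2, a disulfide isomerase of mucus-secreting cells, fell by 2.85 ± 0.26 (7.20-fold lower; adjusted p = 1.12e-06), and PDK4 fell by 2.51 ± 0.32. The other leading rises were R3HDML (3.47), LCE3E (3.31), MMP2 (2.89), RASGRP3 (2.87), SEMA7A (2.85), GXYLT2 (2.70) and the cytokine IL1A (2.51). The other deepest falls were the copper carrier CP (-2.36), the cAMP phosphodiesterase PDE8B (-2.35), the glutathione peroxidase GPX2 (-2.28), the cytokine receptor CRLF2 (-2.26), SPX (-2.25), TM4SF20 (-2.20), FGA (-1.96) and the annexin ANXA13 (-1.94). The rule again took only genes whose 2 groups of arrays did not overlap (chance share 10%).

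Extracellular matrix genes rose in 21 of 39 with 0 fallen and 18 not called at 24 h, 25 adjusted over the list alone (camera adjusted p = 2.58e-19; adjusted p = 0.01 with an estimated correlation). The collagen COL4A1 (2.27), the collagenase MMP1 (2.19), TIMP3 (1.85) and MMP10 (1.73) led. Mesenchymal markers rose in 12 of 18 with 6 not called, 13 adjusted over the list alone, with MMP2, TAGLN (2.22), SPOCK1 (1.57) and SERPINE2 (1.37) leading (camera adjusted p = 1.32e-14; adjusted p = 0.0151 with an estimated correlation). N-cadherin (CDH2) rose by 0.65 ± 0.072 and vimentin (VIM) by 0.62 ± 0.11, whereas fibronectin (FN1) was at 0.39 ± 0.13 and was not called (adjusted p = 0.0622). In log2 intensity FN1 went from 12.29 untreated to 12.13 at 24 h in replicate 1. In replicates 2 and 3 it went from 11.92 to 12.60 and from 11.975 to 12.62. NRF2 target genes fell in 13 of 19 with 1 risen, 17 and 1 adjusted over the list alone (camera adjusted p = 2.95e-12; adjusted p = 0.0234 with an estimated correlation). The aldo-keto reductases AKR1C2 (-1.17) and AKR1B10 (-0.89) and the transporter ABCC2 (-1.04) fell, and HMOX1 rose by 0.78. Of the 14 transcription factors of the epithelial to mesenchymal transition 5 rose and 1 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00174; adjusted p = 0.023 with an estimated correlation). SNAI2 (1.95), SNAI1 (1.34), TCF4 (1.00) and ZEB1 (0.44) rose.

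TGFβ early target genes still had 23 of 33 risen and 0 fallen at 24 h, 24 adjusted over the list alone, among them PDGFB (1.66), ANGPTL4 (1.48), SPHK1 (1.32) and LTBP2 (1.17) (camera adjusted p = 9.43e-17; adjusted p = 0.0624 with an estimated correlation). SMAD7, an inhibitor of the pathway, rose by 0.65 ± 0.15. Integrins and actin cytoskeleton genes had 16 of 33 risen and 2 fallen, 20 and 4 adjusted over the list alone, with ITGB6 (2.00), TNS1 (1.92), ITGB3 (1.66) and ITGA11 (1.43) leading (camera adjusted p = 1.78e-08; adjusted p = 0.0572 with an estimated correlation). Epithelial markers had 10 of 33 fallen and 3 risen, 12 and 3 adjusted over the list alone (camera adjusted p = 0.00184; adjusted p = 0.0624 with an estimated correlation). CDH1 fell by 1.62 ± 0.17 log2 units (3.08-fold lower; adjusted p = 4.33e-06) and FGB by 1.45, while CLDN4 rose by 1.25. Interferon response genes had 6 of 31 fallen and 1 risen, 8 and 2 adjusted over the list alone, with OAS1 at -0.98 and HERC6 at -0.64 (camera adjusted p = 0.0228; adjusted p = 0.347 with an estimated correlation). Sterol biosynthesis genes had 4 of 17 fallen and 0 risen, 4 adjusted over the list alone, with MVD at -0.41 and ACAT2 at -0.36 (camera adjusted p = 0.0228; adjusted p = 0.408 with an estimated correlation). TGFβ receptors and SMADs split, with TGFBR1 (1.38) and BMPR2 (1.103) among 4 risen and TGFBR3 (-1.24) and TGFBR2 (-0.69) among 4 fallen of 18 (5 and 6 adjusted over the list alone; camera adjusted p = 0.801).

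The lists for other themes were not called at 24 h in siControl. Of 18 p53 target genes 4 rose and 1 fell (camera adjusted p = 0.0749), with TP53I3 at 0.86 and GDF15 at -1.74. The stress response list had PSAT1 at -0.60 and PHGDH at -0.59 (adjusted p = 0.124), the NF-kB list had IL1A risen and CXCL5 fallen by 0.97 (adjusted p = 0.218), and the YAP and TEAD list had RBMS3 at 1.24 and ANKRD1 at -1.31 (adjusted p = 0.182). In the BMP list GREM1 rose by 1.09 and BMP4 fell by 1.31 (adjusted p = 0.257), in the polarity list LLGL2 fell by 0.79 (adjusted p = 0.199), and in the hypoxia and glycolysis list VEGFA rose by 0.92 (-0.05 in replicate 1; 1.40 without it) and ALDOC fell by 1.00 (adjusted p = 0.425). Of 35 cell cycle genes, 27 histone and ribosomal protein genes and 10 alveolar type 2 markers, 0 were called by limma at 24 h (camera adjusted p = 0.312, 0.202 and 0.823). Of markers of other cell types, the fibroblast list had LUM, lumican, risen by 1.28 and FBLN2 by 0.41 among 8 (adjusted p = 0.0671), the leukocyte list had CD14 fallen by 0.66 among 9 (adjusted p = 0.341) and the endothelial list had TEK risen by 0.22 among 7 (adjusted p = 0.824). CD14 and TEK were dim at 24 h in siControl, with mean log2 intensities of 6.58 and 6.41, below the median of the arrays. Median and mean differed in sign for the alveolar list (-0.031 and 0.020) and the endothelial list (-0.026 and 0.004).

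At 24 h 1075 genes rose and 1187 fell in siControl, 155 and 122 of them by at least 2-fold. The total of 2262 was 761 without replicate 2 and 755 without replicate 3. At 8 h and 24 h 602 genes rose at both times and 678 fell at both, where independent lists would share 55.6 and 73.4. The 2 comparisons use the same untreated arrays. Their log2 changes correlated at 0.805 across genes, against 0.502 in 100 simulations with no effect, with a covariance of 0.0628 against 0.00713 simulated and a simulated overlap of 0 calls. With 3 untreated arrays these could not be divided into sets of at least 2, so part of the excess may come from the shared controls.

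**Figure D2:**
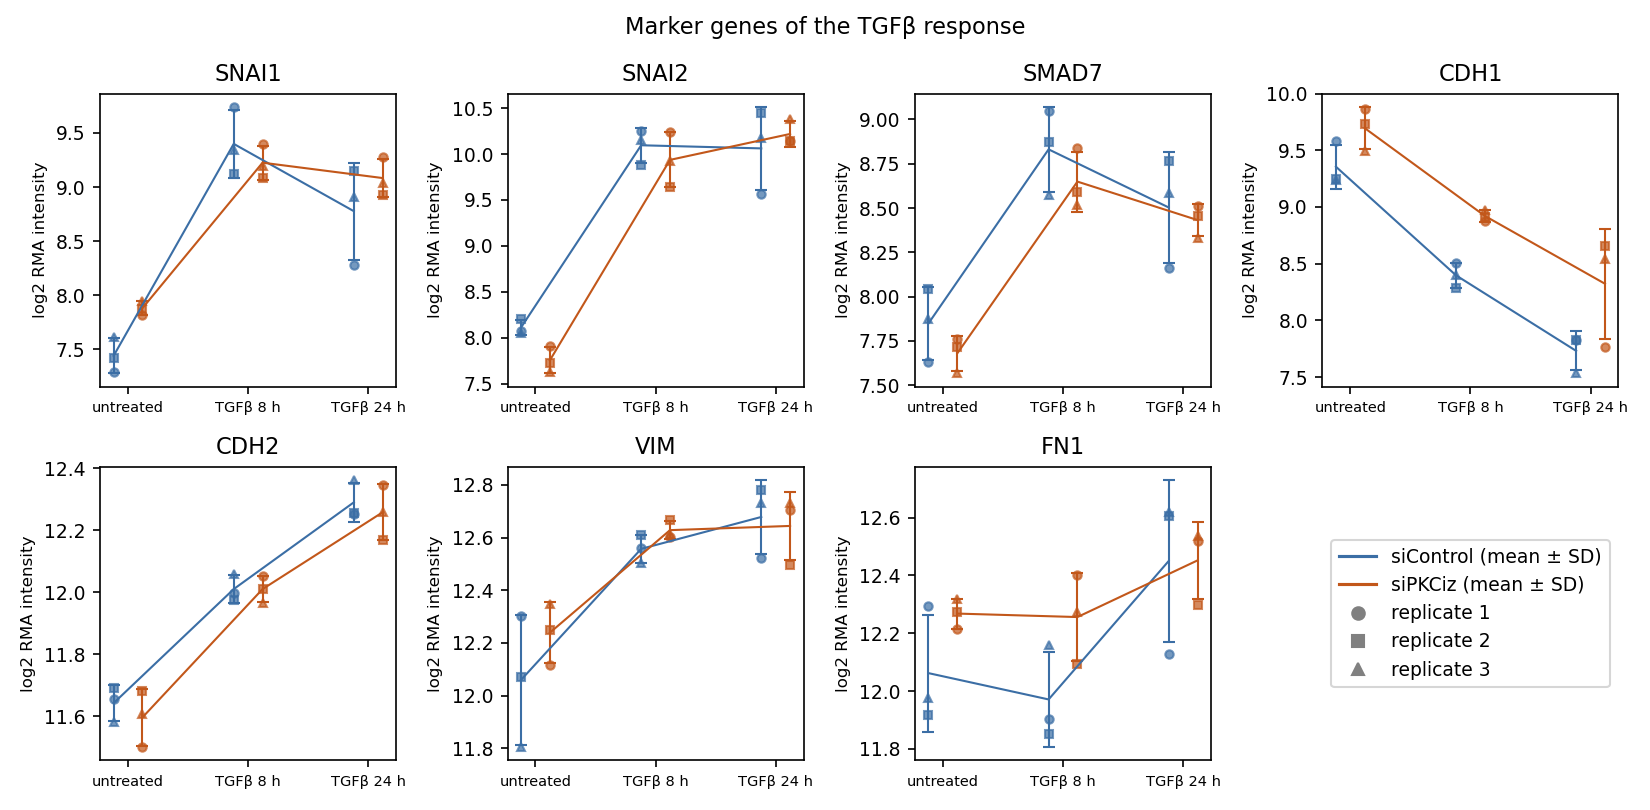
Log2 intensity of the marker genes (vertical axis) by condition in siControl and siPKCiz, each point 1 array, with the mean and SD of 3 arrays. SNAI1, SNAI2, CDH2 and VIM lie higher after TGFβ in both arms, and CDH1 lies lower.

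The 2 times were then compared directly in control cells. HHLA2, a B7 family member, was higher at 24 h than at 8 h by 1.97 ± 0.12 log2 units (SE, n = 3 per group; 3.91-fold; adjusted p = 5.88e-08), followed by the growth factor carrier IGFBP5 (1.91), LCE3E (1.83), SLN (1.71), the protease inhibitor CST1 (1.46), LCE3D (1.45), LUM (1.34), AGMO (1.32), MMP1 (1.26) and BAAT (1.26). ANGPTL4 was lower at 24 h by 1.54 ± 0.37 (2.90-fold lower; adjusted p = 0.0341; -0.76 without replicate 1), with AGR2 (-1.43), GPX2 (-1.39), the fatty acid transporter SLC27A2 (-1.26), the aldehyde dehydrogenase ALDH3A1 (-1.26), PREX1 (-1.17), CPA4 (-1.15), complement C3 (-1.07, and -0.71 without replicate 3), the sodium leak channel NALCN (-1.06) and TBXAS1 (-1.02) also lower. Matrix genes were higher at 24 h in 8 of 39, 15 adjusted over the list alone, including VCAN (0.99) and COL4A2 (0.80) (camera adjusted p = 7.22e-10; adjusted p = 0.12 with an estimated correlation). Mesenchymal markers were higher in 4 of 18, 9 adjusted over the list alone, with MMP2 at 1.03 and SPOCK1 at 0.87 (camera adjusted p = 0.000121; adjusted p = 0.264 with an estimated correlation). NRF2 target genes were lower in 2 of 19, 10 adjusted over the list alone, AKR1C2 (-0.67) and SRXN1 (-0.42) (camera adjusted p = 7.97e-08; adjusted p = 0.174 with an estimated correlation). TGFβ early target genes had 2 of 33 lower at 24 h, 3 adjusted over the list alone, ANGPTL4 and SKI (-0.53) (camera adjusted p = 0.000606; adjusted p = 0.533 with an estimated correlation). Sterol genes had 1 of 17 higher, INSIG1 (0.37) (1 adjusted over the list alone; camera adjusted p = 0.000121; adjusted p = 0.264 with an estimated correlation). CDH1 was lower at 24 h than at 8 h by 0.67 and CDH2 higher by 0.28, whereas SNAI2 (-0.03 ± 0.18) and VIM (0.12 ± 0.11) were not called. The log2 intensity of SNAI2 went from 10.25 at 8 h to 9.56 at 24 h in replicate 1. In replicates 2 and 3 it went from 9.88 to 10.445 and from 10.157 to 10.175. In all 241 genes were higher and 202 lower at 24 h. This total of 443 was 670, 11 and 13 without replicates 1, 2 and 3, and 189 to 288 without 1 array of either group in turn.

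In cells given siRNA against PKCiota and PKCzeta, many of the same genes responded to TGFβ. In replicate 1 of these cells PRKCZ was still at 68.2% to 91.4% of siControl. At 8 h TNFAIP6 rose by 3.00 ± 0.45 log2 units (SE, n = 3 per group; 7.98-fold; adjusted p = 0.000436), SEMA7A by 2.62 ± 0.27, ANGPTL4 by 2.56 ± 0.37, LCE3D by 2.51 and SNAI2 by 2.18 ± 0.18 (4.53-fold). FGA (-1.84), PDK4 (-1.80), SOX2 (-1.67), the sialyltransferase ST8SIA4 (-1.67) and TM4SF20 (-1.67) fell. CDH1 fell by 0.77 ± 0.17, while SNAI1 (1.34), SMAD7 (0.97), CDH2 (0.41) and VIM (0.39) rose. TGFβ early target genes rose in 24 of 33 with 1 fallen, 27 and 1 adjusted over the list alone, with JUNB at 1.40 and IL11 at 1.39 (camera adjusted p = 3.39e-25; adjusted p = 0.0286 with an estimated correlation). Integrin and actin genes rose in 12 of 33 with 1 fallen, 15 and 2 adjusted over the list alone (camera adjusted p = 1.52e-12). Matrix genes rose in 16 of 39 with 0 fallen, 18 and 1 adjusted over the list alone (adjusted p = 1.18e-10), and mesenchymal markers in 8 of 18, 11 adjusted over the list alone (adjusted p = 1.32e-09). These 3 lists and that of the transcription factors (adjusted p = 0.00463) each had adjusted p = 0.0286 with an estimated correlation. At 8 h 575 genes rose and 616 fell. The total of 1191 was 357 without replicate 2, 323 without replicate 3, 691 without the untreated siPKCiz replicate 1 and 668 without the 8 h siPKCiz replicate 1. Of the genes called in both arms at 8 h, 467 rose in both and 473 fell in both, against 29.8 and 38.1 for independent lists, and 0 went opposite ways.

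At 24 h in siPKCiz LCE3D rose by 3.96 ± 0.27 log2 units (SE, n = 3 per group; 15.5-fold; adjusted p = 7.0e-08), SLN by 3.52 ± 0.27 (11.4-fold), TNFAIP6 by 3.28 ± 0.45, MMP2 by 2.68 and R3HDML by 2.67. CP (-2.52), FGA (-2.49), BCAS1 (-2.29), the plasma protein APOH (-2.17) and FGB (-2.13) fell. CDH1 fell by 1.37 ± 0.17, and SNAI2 (2.46), SNAI1 (1.20), SMAD7 (0.75), CDH2 (0.66) and VIM (0.41) rose. Matrix genes rose in 21 of 39 with 0 fallen, 26 adjusted over the list alone (camera adjusted p = 8.88e-23; adjusted p = 0.00496 with an estimated correlation). NRF2 target genes fell in 15 of 19 with 0 risen, 17 and 1 adjusted over the list alone (camera adjusted p = 1.04e-13; adjusted p = 0.0152 with an estimated correlation). The fibroblast marker list rose, with LUM (0.84), PDGFRA (0.67) and FBLN2 (0.34) called among 8 and 3 adjusted over the list alone (camera adjusted p = 0.00247; adjusted p = 0.0245 with an estimated correlation). The cell cycle list was lower with 1 of 35 called, the replication factor GINS2 (-0.31, and -0.18 without replicate 3), and 0 adjusted over the list alone (camera adjusted p = 2.37e-05; adjusted p = 0.41 with an estimated correlation). At 24 h 855 genes rose and 1119 fell. The total of 1974 was 813 without replicate 2, 780 without replicate 3, 1240 without the untreated siPKCiz replicate 1 and 1096 without the 24 h siPKCiz replicate 1. Of the genes called in both arms at 24 h 657 rose in both and 746 fell in both, against 50.01 and 72.28 for independent lists, and 0 went opposite ways; the log2 changes correlated at 0.847 across genes, with no arrays shared.

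**Figure D3:**
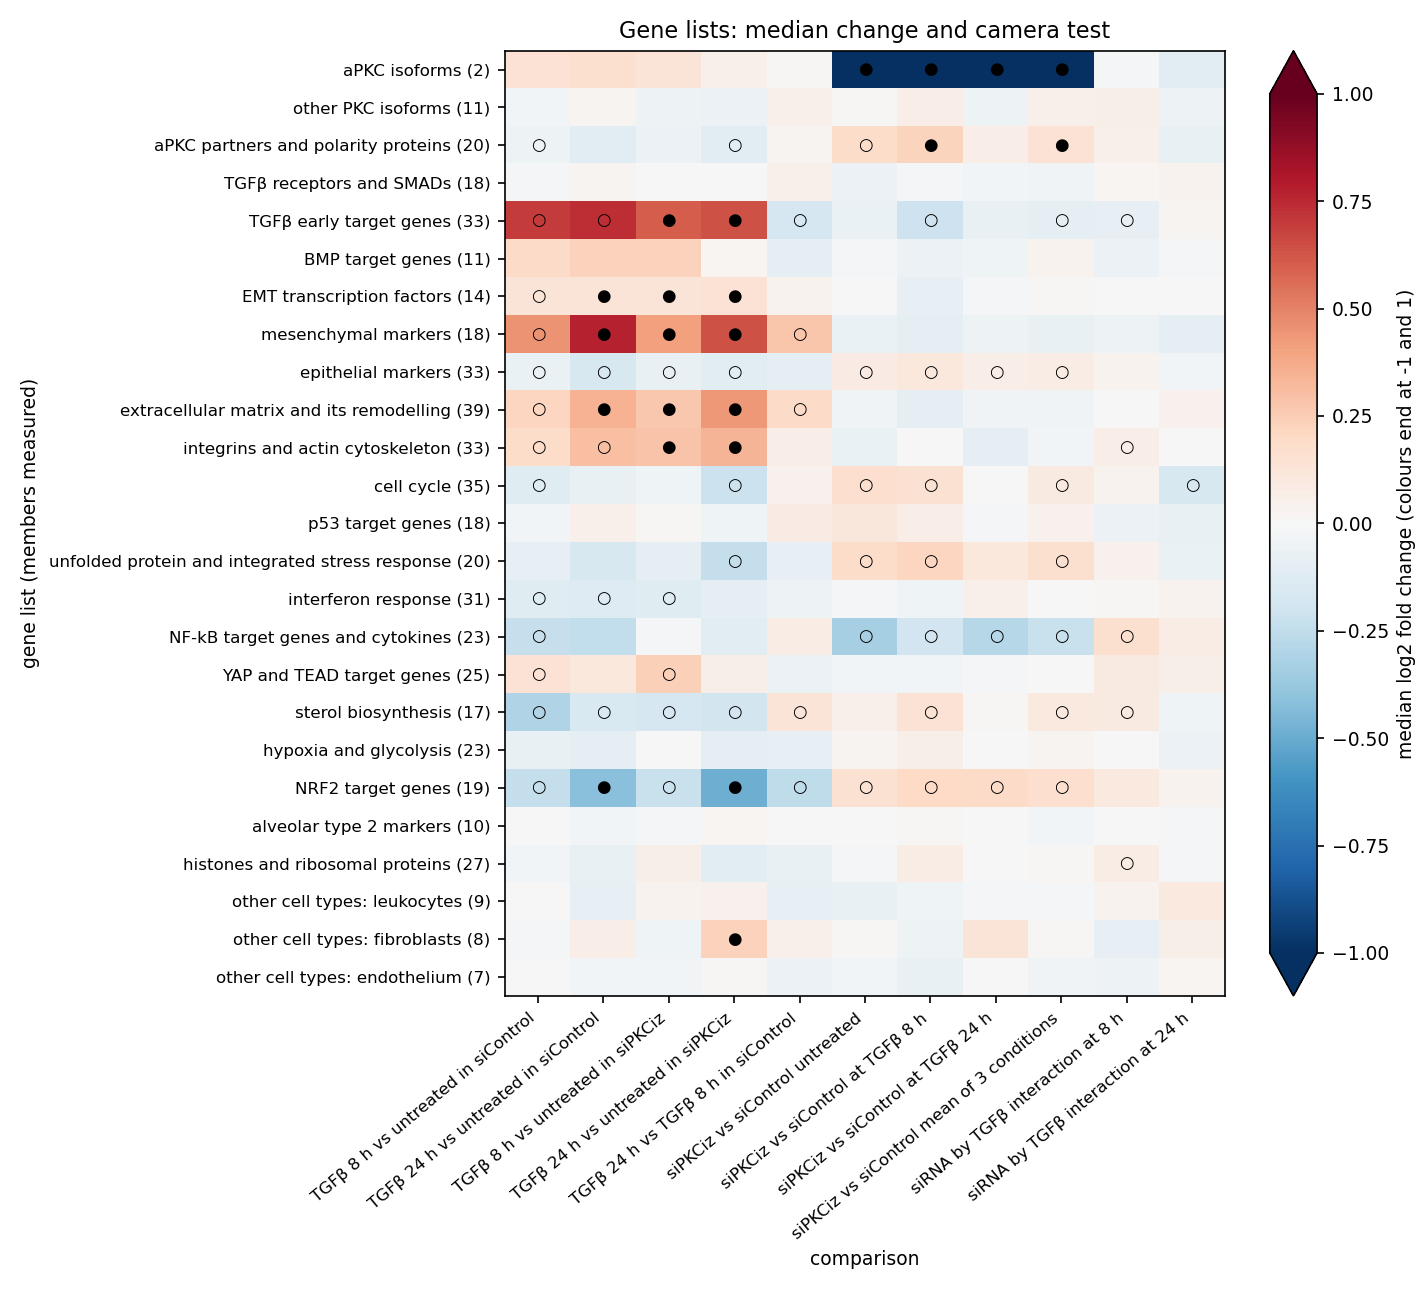
Median log2 change of each fixed gene list (colour, ending at -1 and 1) in each comparison, with the number of members measured beside each name. Filled dots mark lists called by camera that also held with an estimated correlation and open dots those called with the preset correlation only; matrix, mesenchymal and early target lists lie higher after TGFβ and the NRF2 list lower.

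The difference between the arms was then averaged over the 3 conditions. Those after TGFβ are among them, so any difference in the TGFβ response enters this mean. ODAPH, for instance, differed by -1.89 at 8 h of TGFβ, where its interaction was -1.785, though not called. CNN2, calponin 2, an actin-binding protein, was higher in siPKCiz by 1.67 ± 0.065 log2 units (SE; 9 arrays per arm; 3.19-fold; adjusted p = 6.28e-12), and the forkhead factor FOXN3 by 1.41 ± 0.046 (2.66-fold; adjusted p = 3.72e-13). BCAS1 (1.24), the deiodinase DIO2 (1.15), WDTC1 (1.14), the ion channel HCN2 (1.13), cathepsin H (CTSH, 1.08), the transcription factor NFIA (1.08), the stress protein NUPR1 (1.04) and TMCC1 (1.03) were the other leading rises. Beside PRKCI and PRKCZ, TNFAIP6 fell by 1.37 ± 0.26 (2.58-fold lower; adjusted p = 0.00098), the chemokine CXCL8 by 1.21 ± 0.17, the phospholipid acyltransferase LPCAT3 by 1.15 ± 0.18 and the bicarbonate transporter SLC4A8 by 1.13 ± 0.07. RIMOC1 (-1.098), the exocyst component EXOC5 (-1.09), ODAPH (-1.06, and -1.62 without replicate 1) and NCR3LG1, a ligand of natural killer cells (-1.06), also fell. The difference had 1 direction in all 9 pairs of arrays with a shared number for 13 of these 18 genes, PRKCI and PRKCZ apart. In replicate 1 the difference was small for DIO2 (0.097), EXOC5 (-0.20), LPCAT3 (-0.11), TNFAIP6 (-0.068), RIMOC1 (-0.006) and ODAPH (0.043), against means of over 1 log2 unit in size in replicates 2 and 3. The fit took the 9 arrays of an arm as independent, although these differences followed the replicate number. For such genes the standard errors over the 3 conditions are likely too small. Their adjusted p-values, and the count of genes called over the 3 conditions, may be too favourable.

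NF-kB target genes and cytokines fell in siPKCiz in 12 of 23 with 0 risen, 13 adjusted over the list alone, among them CXCL8, IL1A (-1.06), CCL2 (-0.92) and CXCL1 (-0.77) (camera adjusted p = 8.31e-09; adjusted p = 0.124 with an estimated correlation). IL1A differed by -0.35 in replicate 1 and by -1.48 and -1.34 in replicates 2 and 3. NRF2 target genes rose in 11 of 19 with 0 fallen, 12 adjusted over the list alone, including HMOX1 (0.65), GCLM (0.52), AKR1C2 (0.43) and ABCC2 (0.41; 0.23 to 0.64 without 1 replicate) (camera adjusted p = 7.53e-07; adjusted p = 0.124 with an estimated correlation). Partners of the atypical PKCs and polarity proteins rose in 8 of 20 with 0 fallen, 10 adjusted over the list alone, with ECT2 (0.38), CDC42 (0.36), PARD3B (0.31) and RAC1 (0.29) leading (camera adjusted p = 0.000127; adjusted p = 0.0465 with an estimated correlation). Epithelial markers rose in 11 of 33 with 1 fallen, 12 and 1 adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.197 with an estimated correlation). The fibrinogen chains FGA (0.98) and FGB (0.89), EPCAM (0.76) and ELF3 (0.54) led, and CDH1 rose by 0.48 ± 0.098. In replicate 1 the difference was 0.039 for FGA, 0.011 for FGB and 0 for EPCAM, against 0.963 or more in replicates 2 and 3. The stress response list had 7 of 20 risen and 1 fallen, 8 and 1 adjusted over the list alone, with DDIT3 at 0.54 and CEBPB at 0.39 (camera adjusted p = 0.00361; adjusted p = 0.566 with an estimated correlation). Of all 18377 genes 3664 were called over the 3 conditions, a share near those in the early target and cell cycle lists that follow. TGFβ early target genes had 6 of 33 fallen and 2 risen, 7 and 2 adjusted over the list alone (camera adjusted p = 0.00673, and 0.682 with an estimated correlation). IL11 (-0.62), the ubiquitin ligase SMURF2 (-0.57), CCN1 (-0.55) and SPHK1 (-0.54) fell; without replicate 1 CCN1 was at -0.83 and SPHK1 at -0.81. Cell cycle genes had 8 of 35 risen and 1 fallen, 9 and 1 adjusted over the list alone, with KIF20A at 0.34 and CDC25A at -0.36 (camera adjusted p = 0.0157; adjusted p = 0.703 with an estimated correlation). Sterol genes had 5 of 17 risen and 1 fallen, 5 and 1 adjusted over the list alone, with MVK at 0.38 and MSMO1 at -0.37 (camera adjusted p = 0.0209; adjusted p = 0.65 with an estimated correlation).

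Matrix genes had 9 of 39 fallen and 3 risen in siPKCiz, including MMP1 (-0.69) and PLAT (-0.59), and the list was not called (camera adjusted p = 0.0713), nor were mesenchymal markers (adjusted p = 0.0968), where MMP2 fell by 0.60 and SPARC by 0.51. The receptors TGFBR2 (-0.67), ACVR2B (-0.65), TGFBR1 (-0.64) and BMPR2 (-0.54, and -0.82 without replicate 1) fell, with 4 of 18 fallen and 1 risen in that list (adjusted p = 0.22). Integrins and actin genes had ITGA2 fallen by 0.67 and CNN2 risen (adjusted p = 0.576), the p53 list GDF15 risen by 0.95 (0.20 in replicate 1, 1.29 and 1.37 in the others; list adjusted p = 0.27), the hypoxia list SLC2A3 fallen by 0.75 (adjusted p = 0.576) and the YAP and TEAD list NT5E fallen by 0.71 (adjusted p = 0.576). In the transcription factor list ETS1 fell by 0.28 (adjusted p = 0.618), in the BMP list NOG by 0.42 (adjusted p = 0.865), and in the interferon list HERC5 rose by 0.44 (adjusted p = 0.822). Among the cell type lists THY1 fell by 0.65 and LUM rose by 0.55 in that of fibroblasts (adjusted p = 0.822), TEK fell by 0.15 in that of endothelium (adjusted p = 0.565), LAMP3 rose by 0.46 in that of alveolar type 2 cells (adjusted p = 0.75), and 0 of 9 leukocyte markers were called by limma (adjusted p = 0.607). TEK and LAMP3 were dim, with mean intensities below the median of the arrays. Of 27 histone and ribosomal protein genes RPS19 rose, by 0.13 (camera adjusted p for the list = 0.607). CDH2 (-0.03 ± 0.042), VIM (0.07 ± 0.062), FN1 (0.16 ± 0.076), SNAI1 (0.19 ± 0.1), SNAI2 (-0.12 ± 0.1) and SMAD7 (-0.14 ± 0.084) were not called. The median and mean differed in sign for the BMP list (0.032 and -0.013), the transcription factor list (0.011 and -0.020) and the alveolar list (-0.028 and 0.043).

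Over the 3 conditions 2162 genes were higher and 1502 lower in siPKCiz, 12 and 18 of them by at least 2-fold, and the total of 3664 was 5774, 837 and 838 without replicates 1, 2 and 3. In untreated cells 390 were higher and 267 lower, with CYP4F3 (1.28) among the highest and CST1 (-1.18) and HSPA4L (-1.15) among the lowest. This total of 657 was 1513, 30 and 27 without replicates 1, 2 and 3, and 240 to 335 without 1 array of replicate 2 or 3. At 8 h of TGFβ 646 were higher and 349 lower, with ARHGAP29 (1.23) and MUC13 (1.22) among the highest and ODAPH (-1.89), TMEM88 (-1.41) and IL1A (-1.34) among the lowest. That total of 995 was 3486, 35 and 24 without replicates 1, 2 and 3, and 363 to 379 without 1 array of replicate 2 or 3. At 24 h 278 were higher and 309 lower, with AGR2 (1.37), TM4SF20 (1.21) and EPCAM (1.20) among the highest and CXCL8 (-1.36), the potassium channel subunit KCNS3 (-1.23) and the vitamin transporter SLC5A6 (-1.15) among the lowest. This total of 587 was 2078, 18 and 20 without replicates 1, 2 and 3, and 195 to 266 without 1 array of replicate 2 or 3. Over the 3 conditions the replicate 1 difference was small for HSPA4L (-0.042), ARHGAP29 (0.051), TMEM88 (0.20), AGR2 (0.11) and SLC5A6 (-0.28), against over 1 log2 unit in size in replicates 2 and 3. Camera called 7, 9 and 4 of the 25 lists in untreated cells, at 8 h and at 24 h, and 1, 2 and 1 with an estimated correlation. In all 3 conditions 140 genes were called higher and 114 lower.

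**Figure D4:**
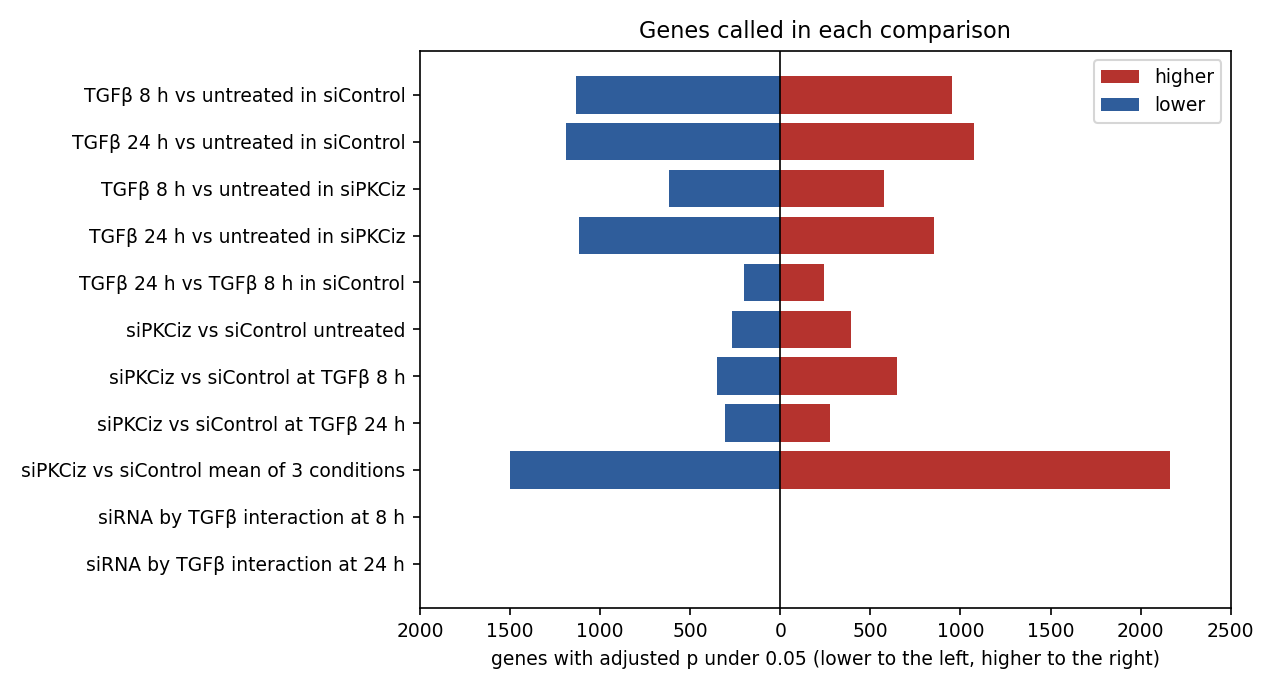
Number of genes higher and lower (limma, adjusted p under 0.05) in each comparison, as bars to the right and left of 0. TGFβ against untreated gave 1191 to 2262 genes, the siRNA arms 587 to 995 within a condition and 3664 over the 3 conditions, and the interactions 0.

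Whether silencing altered the TGFβ response was tested as an interaction, the response in siPKCiz minus that in siControl. With limma 0 of 18377 genes passed at 8 h and 0 at 24 h, and the smallest adjusted p was 0.9997 at both times. At an unadjusted p under 0.05 there were 625 and 705 genes, fewer than the share of 0.05 expected with no effect. At 8 h the difference was -0.61 ± 0.25 log2 units for SNAI1, 0.20 ± 0.25 for SNAI2, 0.18 ± 0.24 for CDH1 and -0.11 ± 0.15 for VIM (SE). At 24 h it was -0.13 ± 0.25 for SNAI1, 0.51 ± 0.25 for SNAI2, 0.25 ± 0.24 for CDH1, -0.21 ± 0.15 for VIM and 0.02 ± 0.1 for CDH2. Without 1 replicate the 24 h values ranged from -0.44 to 0.13 for SNAI1, 0.40 to 0.69 for SNAI2, -0.002 to 0.55 for CDH1, -0.50 to -0.05 for VIM and -0.10 to 0.09 for CDH2, and the 8 h value for VIM from -0.28 to 0.05. In a simulation of this test at 24 h, 35.8% of genes changed by 0.5 log2 units, 82.1% of those changed by 1 and 98.5% of those changed by 2 were recovered. The simulated noise was independent between arrays, with 200 changed genes and no replicate that differed. These shares therefore do not tell how many such differences the real arrays would show. Without replicate 1, 58 genes passed at 8 h and 80 at 24 h. Among the 58 were ODAPH (-2.04), RASGRP3 (-1.94), TMEM88 (-1.27), IL1A (-1.03) and VEGFA (-1.03), each risen less in siPKCiz than in siControl in replicates 2 and 3; these 5 were chosen after their values were seen. Without the 24 h siControl replicate 1 array 3 genes passed at 24 h.

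The size of the response was compared in arrays not used to choose the genes. The 200 genes ranked highest in siControl arrays of 2 replicate numbers were measured in the arrays of the number left out. At 8 h the mean signed change was 1.12 ± 0.22 log2 units (SD, n = 3) in siControl and 0.87 ± 0.25 in siPKCiz, with a ratio of 0.77 ± 0.0639. With the genes ranked in siPKCiz instead the ratio was 0.943 at 8 h and 1.03 at 24 h. At 24 h the changes were 1.28 ± 0.027 and 1.21 ± 0.33, with a ratio of 0.951 ± 0.279; it was 1.27, 0.763 and 0.818 in replicates 1, 2 and 3. With 3 values no p-value is given.

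**Figure D5:**
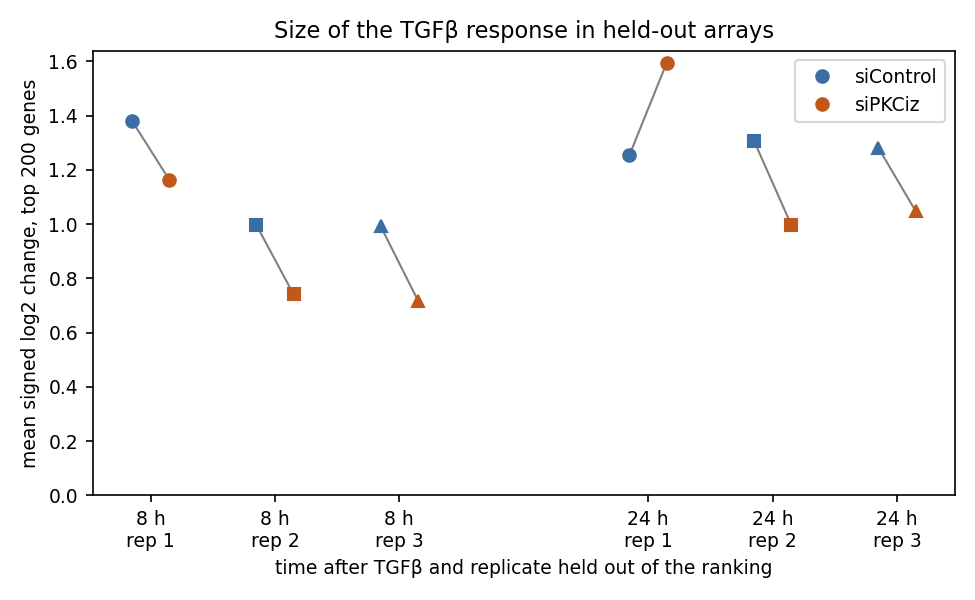
Mean signed log2 change after TGFβ of the 200 genes ranked in the other replicates (vertical axis), in siControl and siPKCiz, for each time and held-out replicate. At 8 h siPKCiz lies lower in each replicate (ratios 0.724 to 0.843), and at 24 h it lies higher in replicate 1 (1.27) and lower in the others.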

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

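The comparisons of patterns below, the bounds used in them and the tests of replicate 1 were chosen after the results had been seen; the regrouping of arrays was planned before.

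In 6 gene lists the test of a difference in TGFβ response between the siRNA arms passed by camera. At 8 h the change was lower in siPKCiz for TGFβ early target genes (camera adjusted p = 0.0314), and higher for integrins and actin genes (0.0412), NF-kB target genes and cytokines (0.00503), sterol biosynthesis genes (0.0314) and histones and ribosomal proteins (0.0412). At 24 h it was lower for cell cycle genes (adjusted p = 0.000172), with a median of -0.16 log2 units. Without replicate 1 the histone and ribosomal list turned lower (adjusted p = 0.855), those of integrins (0.466), sterol genes (0.161) and cell cycle genes (0.0532) kept their direction without passing, and those of early target genes (0.00278) and NF-kB target genes (0.00788) passed. None passed with an estimated correlation (the lowest adjusted p was 0.862) or with fry (the lowest 0.883), and 0 single genes of these lists were called. A signal was also seen outside the genes tested: of 9559 probe sets with several gene symbols or none listed, 148 were called by limma for TGFβ at 24 h in siControl.

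Regrouping the arrays gave 10 ways for each comparison of 3 against 3 arrays, and 1 of 10, the real grouping, called as many genes as observed. With 10 ways the share cannot fall under 0.05. The real count and the highest other were 2087 and 0 at 8 h and 2262 and 3 at 24 h in siControl, 1191 and 0 at 8 h and 1974 and 0 at 24 h in siPKCiz, and 443 and 1 for 24 h against 8 h. For siPKCiz against siControl they were 657 and 0 untreated, 995 and 1 at 8 h, and 587 and 222 at 24 h. Over the 3 conditions together 1 of 100 regroupings, the real one, reached 3664 genes, and the highest other reached 236. The arrays were regrouped separately within each condition, which broke up arrays of the same number. Differences that followed the replicate number, as that of PRKCZ did, were thus not kept together, so this share cannot exclude chance. For the interactions, with 0 genes called, 100 of 100 regroupings called as many at 8 h and at 24 h, as must follow from a count of 0.

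Without replicate 1, 80 genes passed the interaction test at 24 h, against 0 with all arrays at equal weight, 1 with array weights and 3 without the 24 h siControl replicate 1 array; ODAPH (-2.27), RASGRP3 (-2.17) and IL1A (-2.05), named after their values were seen, were among the 80. With the replicate number as a factor 0 genes passed, which argued against a shift shared by all replicate 1 arrays. Over the 2262 genes called at 24 h in siControl the siPKCiz response of replicate 1 was 1.52 times that of replicates 2 and 3. In siControl it was 0.903 times, so a weaker lowering of PRKCZ there may have contributed. Over the genes called at 8 h these ratios were 1.52 and 1.15. At 24 h the replicate 1 response was 0.657 log2 units in siPKCiz. In siControl it was 0.571, 0.633 and 0.632 in replicates 1, 2 and 3. A return towards the siControl response would not by itself carry siPKCiz beyond it. A weaker lowering of PRKCZ would move the siPKCiz response. Replicate 1 narrowed the gap more through siPKCiz in 38 of the 80 genes, such as RASGRP3 (3.40, 0.73 and 0.55 in siPKCiz and 3.02, 2.96 and 2.65 in siControl in replicates 1, 2 and 3). It did so more through siControl in 42, such as ODAPH (0.81, 3.47 and 3.12 in siControl) and IL1A (1.20, 3.32 and 3.02). The 80 genes were chosen for passing without replicate 1, so a narrower gap there was built into the choice. This split therefore cannot weigh the part of PRKCZ, which stays open. Of the regroupings of the arrays left, that giving 3369 genes exchanged the arms in 1 condition, which turns the difference between the arms into an interaction and bears on no chance likeness; the highest of the rest gave 51 against the real 80, and 18 regroupings are too few for a share under 0.05.

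Of 77 genes that differed by at least 1 log2 unit between the arms in replicates 2 and 3, 48 had a replicate 1 difference of at most 0.25 of theirs, LPCAT3, RIMOC1 and TNFAIP6 among them. The PRKCI ratio was 1.08, which argued against a weaker effect of the whole siRNA treatment in replicate 1. The median ratio was 0.145, beside 0.222 for PRKCZ, so these changes may depend on the loss of PRKCZ. A choice on replicates 2 and 3 favours small ratios, and 10 of the 77 had a ratio of at least 0.75. A choice on replicate 1 would favour small ratios the other way round, yet 9 of 17 such genes had at least 0.75. The choice alone therefore does not readily account for the small ratios. Of the 48 genes 68.8% were lower in siPKCiz, too mixed to count for or against an siRNA that also silenced other messages. Loss of PRKCZ and such silencing both stay open.

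The 18 genes named over the 3 conditions had been weighed first, and gave another answer. Their median ratio was 0.848, which argued against loss of PRKCZ as the source of all 18, although 6 of the 18 had ratios of at most 0.5 and a choice on the mean of all replicates favours ratios near 1; the 77 genes were taken up after this was seen. Of the 18 genes 44.4% were lower and 55.6%, such as CNN2 and FOXN3, higher, shares set by a rule that took 10 genes each way before PRKCI and PRKCZ were left out. They therefore said nothing on silencing of other messages, whether by the siRNAs to PKCiota and PKCzeta or by the control siRNA, and both could have contributed; arrays of cells without siRNA were not used here.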

How the results depend on the processing

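Of 631 results of called genes named by the rule 0 changed sign under any alternative, a weak test for genes chosen for large changes. Of 307 of genes named but not called 54 did, such as, without replicate 1, SNAI1 (-0.04), SNAI2 (-0.05) and FN1 (-0.19) for the arms at 24 h. Among the named genes, leaving out a replicate number lost 725 calls, gained 77 and left 2012 results the same. Leaving out 1 array lost 685 calls, gained 41 and left 6858 the same. Genes named outside the rule were not refitted. Leaving arrays out lowers the degrees of freedom, yet 9 of 11 counts rose without replicate 1, and the cause was not tested, nor was that of the other shifts. The leave-outs of the held-out ratios were chosen after the data were seen. With array weights the genes called were 3485 and 3483 for TGFβ at 8 h and 24 h in siControl, 1871 at 8 h in siPKCiz, 2956, 2929 and 1228 for siPKCiz against siControl untreated, at 8 h and at 24 h, 5987 over the 3 conditions and 1 for the interaction at 24 h. With a fold change of at least 1.5 added, they were 743 and 845 in siControl, 484 and 726 in siPKCiz, 154 for 24 h against 8 h, 194, 237 and 175 for the arms by condition and 199 over the 3 conditions. With only the arrays of the groups compared they were 211 for 24 h against 8 h, 229 for the arms at 24 h and 2 for the interaction at 8 h. The held-out ratio was 0.943 at 8 h and 1.03 at 24 h with genes ranked in siPKCiz, and 0.733 to 0.793 and 0.79 to 1.04 without 1 replicate.

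With the replicate number as a replicate block the genes called were 262 for 24 h against 8 h, 616 for the arms at 8 h and 380 at 24 h; it lost 61 calls on named genes, kept 877 results, changed 0 of 275 list results and no other count by over 1.5 times. Of 45 pairs of arrays with the same number in different groups 7 correlated above 0.1 (from -0.514 to 0.258), and 0 of 18 arrays correlated best with their own number. Yet replicates 2 and 3 were the closest in 6 of 6 groups, so replicate 1 stood apart in each group. It did not deviate alike in all of them, as the correlation of -0.514 was between replicate 1 arrays of the 2 arms. PRKCZ differed between the arms by -0.32, -1.41 and -1.48 in replicates 1, 2 and 3 (mean of the 3 conditions). Its smaller difference in replicate 1 was seen in each condition.

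Without 1 replicate at a time (lowest to highest) the genes called were 681 to 2917 and 755 to 2872 for TGFβ at 8 h and 24 h in siControl, 323 to 1123 and 780 to 1737 in siPKCiz, 11 to 670 for 24 h against 8 h, 27 to 1513, 24 to 3486 and 18 to 2078 for the arms untreated, at 8 h and at 24 h, 837 to 5774 over the 3 conditions, and 0 to 58 and 0 to 80 for the interactions. The lists that turned direction did so without replicate 1: histones and ribosomal proteins in the 8 h interaction (camera adjusted p = 0.855, range 0.000146 to 0.855), TGFβ early target genes (0.00606, range 0.00606 to 0.833) and integrins and actin genes (0.0443, range 0.0443 to 0.931) in the 24 h interaction. An estimated correlation lost 62 of 275 list results. Only called lists could be lost, so this was most of the calls. At 8 h in siControl camera called 13 lists, and 0 held with an estimated correlation. With fry 21 were lost and 12 gained, the filter on dim probe sets lost 21 and gained 12, and quantile normalization lost 11 and gained 7.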

Other observations

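Genes were also grouped by the stem of their symbols, 311 stems in all, a grouping chosen after the gene lists had been read. At 24 h of TGFβ in siControl the DOCK exchange factors were higher, with 6 of 11 risen and 1 fallen, DOCK2 by 1.88 and DOCK4 by 1.30 log2 units (camera adjusted p = 0.0244; adjusted p = 0.979 with an estimated correlation). The histone demethylases of stem KDM had 4 of 18 risen, KDM6B by 1.41 and KDM7A by 0.85, and the aldehyde dehydrogenases of stem ALDH had 6 of 19 fallen, ALDH3A1 by 1.76 (adjusted p = 0.0244 for each; 0.979 for each with an estimated correlation). The HOXB genes were lower with 2 of 10 fallen, HOXB8 by 1.34 (adjusted p = 0.0472), and mitochondrial ribosomal proteins of stem MRPS had 4 of 26 fallen, MRPS18B by 0.46 (adjusted p = 0.0244); both had adjusted p = 0.979 with an estimated correlation.

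At 24 h in siPKCiz DOCK2 rose by 1.77 and DOCK4 by 1.21 (camera adjusted p for the DOCK stem = 0.000595; adjusted p = 0.304 with an estimated correlation), and HOXD10 rose by 1.32 and HOXD11 by 0.93 (HOXD stem, adjusted p = 0.0101; adjusted p = 0.445 with an estimated correlation). The nicotinic receptor subunits CHRNA9 and CHRNA3 rose by 2.15 and 1.02 (CHRNA stem, adjusted p = 0.0209; adjusted p = 0.384 with an estimated correlation). Over the 3 conditions siPKCiz had 15 of 34 genes of the vacuolar sorting stem VPS risen and 2 fallen, with VPS50 at 0.32 and VPS4B at -0.53 (adjusted p = 0.00592; adjusted p = 0.78 with an estimated correlation).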
